A study of Mus musculus with 2 samples.

How the data were processed

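Cells were released from crushed femurs after removal of the bone ends and the marrow, depleted of immune and erythroid cells by sorting, and profiled with the Chromium GEM-X 3′ chemistry, per the labels' protocols. Cells of 2 mice per genotype were pooled before capture, so each genotype is 1 library and the mice of a pool cannot be told apart. The deposited values are whole-number counts of UMIs per gene and barcode, without normalization, in matrices already filtered to barcodes called as cells by the authors. Cell Ranger 9.0, Seurat 5.4 and the mm10 build are named in the submitters' processing notes, and the steps done with each are not given in the sources used here. The matrices list 33696 features, of which 32012 carry an ID of GENCODE M21 on GRCm38 and 1684 carry an ID outside it. Gene symbols were taken from the matrices, and positions from GENCODE M21 on GRCm38, the assembly that mm10 names. Strand handling and the treatment of reads shared between copies are not given in the sources used here.

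Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. The gene and UMI minimum removed 176 control and 227 Notch2em1Ecan barcodes, and the mitochondrial maximum a further 62 and 67. Doublets were called per library with Scrublet in scanpy 1.11.5, which removed 5 control barcodes (0.515%) and 13 Notch2em1Ecan barcodes (0.610%). This low rate may leave doublets that the caller did not see, which were not measured. The kept cells held 9824322 control and 17182636 Notch2em1Ecan UMIs, with medians of 2228.5 and 1963 genes per cell. Both libraries held Xist (6561 and 10297 UMIs) and almost no UMIs of 4 Y-linked genes (1 and 2), as the female labels require.

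Cells of both libraries were clustered together without batch correction on 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1, with random seed 0. Clusters were named from 25 marker lists, as resemblance to a cell type. The markers were fixed in advance, but the planned skeletal muscle list was split into a progenitor and a fibre list, without Musk. A cluster took the name of the list with the highest mean score. It stayed unnamed where another list had more markers among its 10 leading genes, which left 11 barcodes of each library unnamed. It took both names where the next list scored close to the best, which kept the osteoblast-lineage-like and leptin-receptor-stromal-like cells of 1 cluster together. Those cells and the osteoblast-lineage-like cluster were clustered again to separate osteogenic from stromal cells. Raw UMIs were summed per library and class and scaled to a common total per class (CPM). Cells were not treated as replicates, and no p-value was computed.

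The marker lists before the split of the muscle list, the 31 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. In each class with at least 30 cells per library, the named genes are those with at least 50 UMIs over both libraries, a UMI in at least 10% of cells of the library where they are higher, no single cell holding most of their UMIs, and a fold of at least 1.5. Of these, the 12 highest and 12 lowest were taken, ranked by the bound of the 95% counting interval nearest to no difference. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked and unnamed genes, and markers of haematopoietic classes, were left out of this ranking. Not every gene the rule takes is reported here. Notch receptors, ligands and core targets with at least 20 UMIs were added in every class, as were up to 4 members of each gene list. Fold intervals are exact conditional binomial intervals, shares have exact Clopper-Pearson intervals, and levels have exact Poisson intervals; all cover counting error only. A fold against 0 UMIs is a lower bound at a floor of 3 counts. A list's value is the median log2 fold of its members with at least 20 UMIs, with an interval from resampled counts, and its percentile is among 10000 random lists of the same size matched on expression. Counts of members at least 1.5 times apart are by size alone.

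The steps were tested on simulated data drawn from the real levels and depths, with 67, 67 and 66 genes set apart by 1.5, 2 and 4 times. Class totals were drawn with counting error alone from 1 shared profile, without spread between cells or a change in cell mix. The naming rule ran without its limits on cells. The shares below therefore speak to counting error only. For endothelial-like cells (10770 genes), the interval held no difference for 95.8% of unchanged genes, and left it out for 64.2%, 91.0% and 100% of genes at the respective folds. The shares were 96.1%, 56.7%, 95.5% and 98.5% in mural-like cells (8308 genes). In the mixed osteoblast-lineage and stromal class (5773 genes) they were 96.1%, 50.7%, 76.1% and 100%. All 24 named genes had the right sign in each of these 3 classes. A list of 10 raised genes with a median log2 fold of 1 was recovered at 0.87, 0.93 and 0.87. A list of 10 unchanged genes gave 0.083, 0.18 and −0.28, at percentiles 87.7, 95.7 and 5.17 of matched random lists, so a median of this size can arise from counting error alone.

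Alternatives covered mitochondrial maxima of 5% and 20%, looser and stricter minima on genes and UMIs, doublets kept, resolutions of 0.5 and 2, another seed, assignment of each cell alone, TMM scaling with edgeR 4.0.16, scaling without mitochondrial, ribosomal and haemoglobin genes, equal weight per cell, and cells thinned to 2000 UMIs. Of the list medians, only 14 were run under these alternatives, in the endothelial-like, mural-like, osteoblast-lineage-like and mixed classes. For the same 14, member minima of 5 and 100 UMIs and the mean were tried, and for named genes minima of 20 and 200 UMIs. Added after the data were seen were endothelial-like cells without the lymphatic cluster, the same mix of clusters in both libraries for endothelial-like, erythroid-like, fibre-like, progenitor-like, osteogenic and leptin-receptor-stromal cells, subtraction of fibre RNA (which gives no value for a gene it takes to the floor of 3 counts in either library), the osteogenic sub-clusters, the mural clusters apart, mural-like cells without those richest in fibre transcripts, and each gene without the 5 cells holding most of it. For the last of these, the 5 cells were picked by the gene's own UMIs over both libraries. Their removal thus falls mostly on the library that holds them, and can by itself shrink or turn a fold. Work was done in Python 3.11.15 with anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3.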

Results

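Single-cell RNA sequencing was carried out on cells released from the femurs of control mice and of mice carrying the Notch2em1Ecan allele, to ask how a NOTCH2 pathogenic variant alters the transcriptome of osteoblasts and vascular cells in bone. Each library held cells pooled from 2 female mice aged 6 to 9 months, depleted of CD45- and TER119-positive cells by sorting. The control library held 10204964 UMIs in 1209 barcodes, with a median of 4882 UMIs per barcode. The Notch2em1Ecan library held 17872056 UMIs in 2424 barcodes, with a median of 5276. After filtering, 966 control and 2117 Notch2em1Ecan cells remained, with medians of 6377.5 and 5904 UMIs per cell. There was 1 library per genotype, so no difference reported here has a replicate check and no test between genotypes was made. Values are log2 folds of Notch2em1Ecan over control in CPM, UMI counts scaled to a common library total, summed over the cells of a class. Brackets hold exact 95% intervals, which cover counting error only.

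Clusters were named from fixed markers, and each name is only a resemblance to a cell type. Endothelial-like cells made up 30.1% [27.2 to 33.1] of control cells (291 cells) and 34.7% [32.6 to 36.7] of Notch2em1Ecan cells (734 cells). Mural-like cells, the pericytes and smooth muscle cells around vessels, made up 11.3% [9.36 to 13.5] (109 cells) and 5.57% [4.63 to 6.64] (118 cells). Muscle-fibre-like barcodes made up 23.2% [20.6 to 26.0] of the control library and 35.8% [33.7 to 37.8] of the Notch2em1Ecan library, and they lower every other share. With fibre-like, haematopoietic-like and unnamed barcodes left out, endothelial-like cells made up 45.4% [41.5 to 49.3] of 641 control cells and 58.0% [55.2 to 60.7] of 1266 Notch2em1Ecan cells. Mural-like cells then made up 17.0% [14.2 to 20.1] and 9.32% [7.78 to 11.1]. Muscle-progenitor-like cells were 11.1% [9.17 to 13.2] of all control cells and 8.79% [7.61 to 10.1] of Notch2em1Ecan cells, and fibroblast-like cells were 6.21% [4.77 to 7.92] and 4.16% [3.35 to 5.10]. The osteoblast-lineage-like cluster held 7 control and 18 Notch2em1Ecan cells, or 0.725% and 0.850%. A mixed cluster of osteoblast-lineage-like and leptin-receptor-stromal-like cells held 39 and 40 cells. Cells that the sort and the red cell lysis deplete remained as 86 and 60 erythroid-like and 4 and 23 mixed haematopoietic-like cells. The crushing, digestion and sorting of the bones can set any of these shares.

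**Figure D1:**
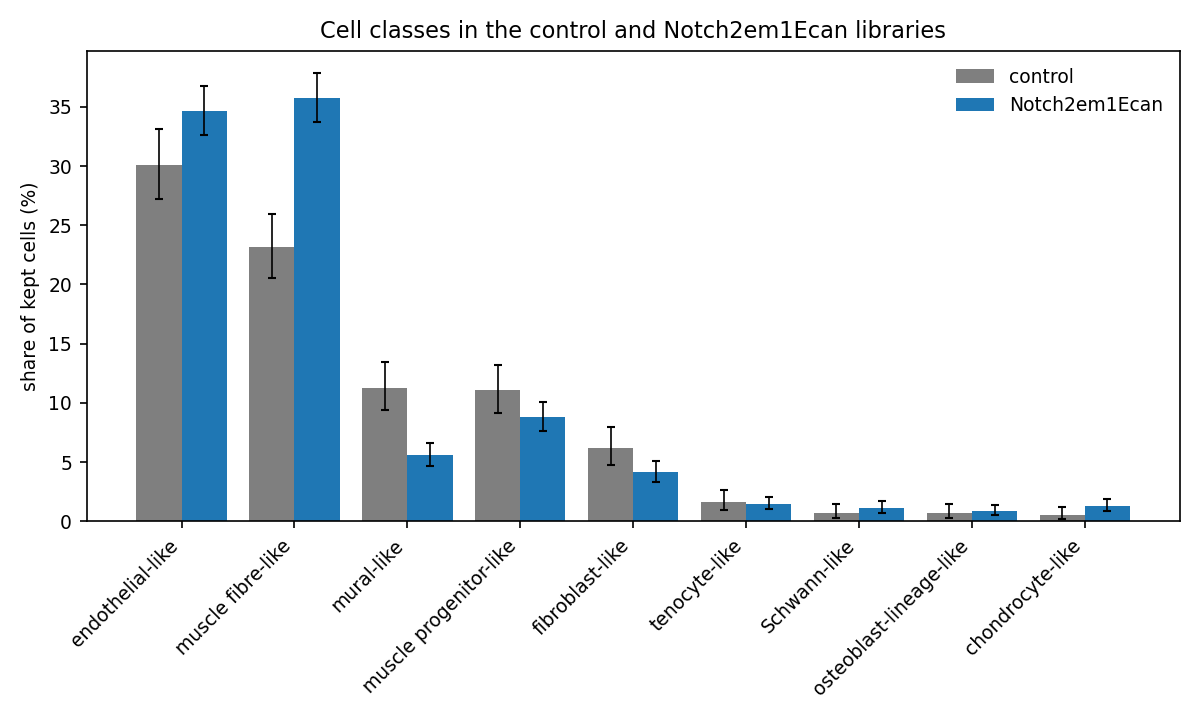
Share of kept cells in each class apart from mixed, haematopoietic and unnamed ones, in percent, for the control library and the Notch2em1Ecan library; bars are shares and lines are exact 95% binomial intervals for counting error only. Mural-like cells made up 11.3% of control and 5.57% of Notch2em1Ecan cells, and muscle-fibre-like barcodes 23.2% and 35.8%.

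Notch2 (ENSMUSG00000027878), which encodes the altered receptor, lies on the plus strand of chromosome 3 at 98013527 to 98150361 in GRCm38. Its transcript was sparse. Endothelial-like cells held 7 control and 14 Notch2em1Ecan UMIs, or 4.61 and 3.88 CPM, a fold of 0.842 [0.318 to 2.46]. Without the 5 cells holding most of them the log2 fold was 2.31, from 1 and 12 UMIs, since the removal fell mostly on control UMIs. The log2 fold was −0.27 [−1.27 to 0.72] in mural-like cells, −0.50 [−1.31 to 0.30] in the mixed osteoblast-lineage and stromal class, 0.39 [−1.03 to 2.14] in osteoblast-lineage-like, −0.33 [−0.83 to 0.18] in fibroblast-like and −0.31 [−0.69 to 0.08] in muscle-progenitor-like cells. Erythroid-like cells gave −1.05 [−2.03 to −0.16], or 0.29 when each cell had the same weight. Muscle-fibre-like barcodes held 0 and 4 Notch2 UMIs, too few for a fold at these counts. The labels do not say what the allele changes, so it is not known whether the counted 3′ tags lie in the altered part. Notch2 levels therefore do not check the genotype labels.

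Hes1, a transcriptional repressor induced directly by Notch receptors, was lower in the Notch2em1Ecan library in 5 classes with intervals below 0. It stood at −0.38 [−0.50 to −0.26] in endothelial-like, −0.50 [−0.62 to −0.37] in mural-like, −0.58 [−0.83 to −0.32] in fibroblast-like and −0.38 [−0.54 to −0.21] in muscle-progenitor-like cells. In the mixed class it was −0.67 [−1.01 to −0.34], and −0.09 without the 5 cells richest in it. Osteoblast-lineage-like cells went the other way at 2.65 [1.04 to 4.96], from 3 control and 69 Notch2em1Ecan UMIs, 69.4% of them in 5 cells, without which the value was 1.37. Under settings where no mixed class formed, the class held other cells, and the value was 0.38 with a 5% mitochondrial maximum (13 control and 30 Notch2em1Ecan cells), 0.26 with looser minima (28 and 41), 0.25 with at least 1000 genes per cell (23 and 43) and 0.69 with each cell assigned alone (19 and 37). Its difference from the other classes was not tested. Hey1, a Notch-induced repressor tied to arterial identity, was 1.68-fold higher in endothelial-like cells, a log2 fold of 0.75 [0.43 to 1.09]. In endothelial-like cluster 3, picked from 7 such clusters, Hey1 was 3.17-fold higher (1.67 [1.16 to 2.21]). Jag1, which encodes a Notch ligand, was 2.15-fold higher there (1.10 [0.67 to 1.55]). The values of the other clusters are not given here, and a different mix of cells within cluster 3 was not tested. Over all endothelial-like cells Jag1 was at 0.32 [−0.04 to 0.70], Nrarp, a Notch feedback regulator, at 0.26 [0.00 to 0.53], Notch1 at 0.08, Dll4 at 0.04 and Notch4 at −0.05.

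In mural-like cells Notch3, the receptor that maintains vascular smooth muscle, was at −0.32 [−0.52 to −0.11], and at 0.02 once every cell was thinned to 2000 UMIs. Nrarp was lower at −0.57 [−0.88 to −0.26], but stood at 0.15 with the mitochondrial maximum at 5% and at 0.04 in the pericyte-like cluster alone. Heyl and Hey2 were at 0.08 and 0.25. Hey1 was no higher than Hes1, since the median of the measured core genes lay at the −0.50 of Hes1. After thinning Hey1 stood at 1.33, from 2 control and 6 Notch2em1Ecan UMIs. Muscle-progenitor-like cells, in which Notch signalling maintains quiescence, had lower Jag1 (−1.04 [−1.56 to −0.52]), Notch1 (−0.49 [−0.80 to −0.18], or −0.33 without 5 cells with an interval that holds no difference) and Notch3 (−0.42 [−0.64 to −0.19]), and higher Dll1 (1.11, or −0.25 after thinning, from 4 and 6 UMIs).

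**Figure D2:**
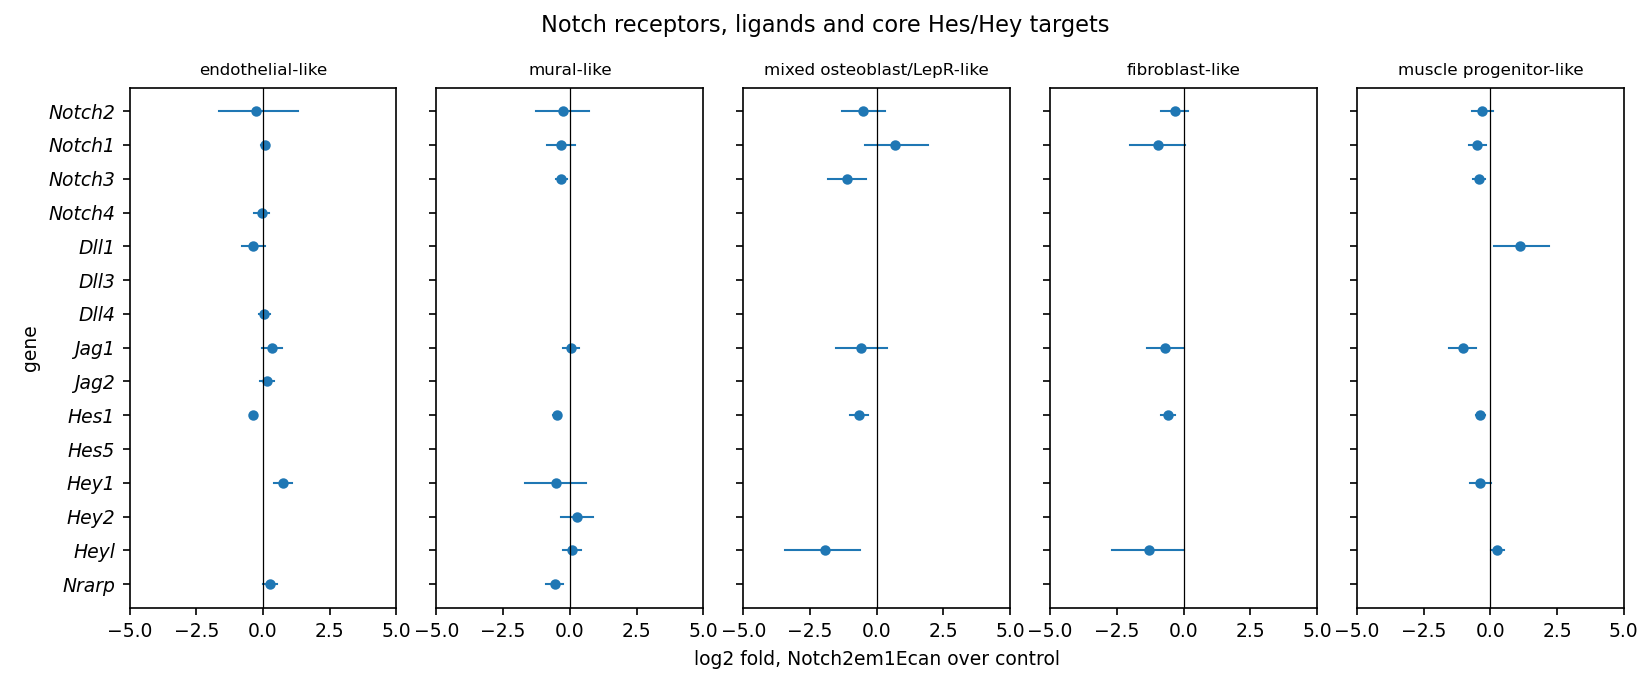
Log2 fold of Notch receptors, ligands and Hes/Hey genes with at least 20 UMIs in 5 classes; points are Notch2em1Ecan over control and lines are 95% counting intervals. Hes1 lies at −0.38 in endothelial-like and −0.50 in mural-like cells, and Hey1 at 0.75 in endothelial-like cells.

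Endothelial-like cells, summed to 1518131 control and 3607594 Notch2em1Ecan UMIs, bore on the vascular side of the question. Muscle-like barcodes were in the same libraries, so endothelial-like and mural-like cells may come from muscle as well as bone, which was not tested. Gpihbp1 and Fabp4 were among the leading genes of cluster 4 (53 control and 228 Notch2em1Ecan cells) and cluster 14 (94 and 268). Cluster 17, with the sinusoidal gene Stab2 among its leading genes, held 10 and 18 cells. Depp1, which FOXO factors induce, was 3.32-fold higher in the Notch2em1Ecan library [2.85 to 3.89]. Klf2, a transcription factor induced by shear stress, was 1.62-fold higher [1.52 to 1.72], and S100a16 and S100a6, which encode calcium-binding proteins and lie within 10 Mb of Notch2, were 2.09-fold and 1.58-fold higher. Plvap, which forms the diaphragms of endothelial fenestrae, was lower at −1.19 [−1.33 to −1.05], or −0.60 with 1 mix of clusters in both libraries, and Lars2, the mitochondrial leucyl-tRNA synthetase, at −0.73 [−0.79 to −0.67]. Other named genes that were higher were Lpin2, a phosphatidate phosphatase (1.34), Cyp26b1, which degrades retinoic acid (0.96), Hspa1a, an inducible heat-shock protein (0.94), Pxdc1 (0.92), and Tpm3 (0.69). Tpm2, a tropomyosin also made by muscle fibres, was at 0.72, and no level was left in either library after fibre RNA was subtracted. Named genes that were lower included Dbp, an output gene of the circadian clock (−1.60), Specc1 (−1.30), H2-Q6 (−1.27) and Csf2rb, the shared chain of the IL-3 and GM-CSF receptors (−1.23). Mgp, an inhibitor of mineralisation, was lower at −1.73, as were Upp1 at −1.42 and Fam167b at −1.04; without the 5 cells richest in each gene these stood at −0.26, −0.54 and −0.34.

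The named genes furthest apart were nearly missing from 1 library. Ptpn22, a tyrosine phosphatase at 103859795 to 103912247 on chromosome 3, had 139 control and 6 Notch2em1Ecan UMIs in endothelial-like cells (−5.78 [−7.25 to −4.62]). Tpm3-rs7, a copy of Tpm3 on chromosome 14, had 341 and 19 UMIs (−5.41), while Tpm3 itself, on the same chromosome as Notch2, was higher. Rnaset2b had 3 and 83 UMIs, a fold of 11.6 [3.85 to 57.6]. Tpm3-rs7 and Rnaset2b have near-identical copies, and Hspa1a and H2-Q6 close relatives in their families. Reads could be split between such copies, which was not tested for Hspa1a and H2-Q6, so the levels of each are uncertain.

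Among the fixed endothelial lists, genes of sinusoidal and venous endothelium were lower by the most. Their median log2 fold was −0.38 [−0.48 to −0.25], at percentile 0 among 10000 random lists of the same size matched on expression, which describes these libraries only. By size alone, 6 of the 20 measured members were at least 1.5 times lower and 0 higher. Beside Plvap these were Lyve1 (−1.62), Gpr182 (−1.25), Dnase1l3 (−1.09), Maf (−0.92) and Ackr1 (−0.86), whereas the scavenger receptor gene Stab2 was at −0.14. Plvap is among the leading genes of endothelial-like cluster 3 and, with Stab2, of cluster 17, and Lyve1 of cluster 18. Cluster 3 made up 22.3% of control and 14.3% of Notch2em1Ecan endothelial-like cells, cluster 17 3.44% and 2.45%, and cluster 4 18.2% and 31.1%. With the same mix of clusters in both libraries the list's median was −0.15, and with thinned cells it was −0.65.

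The interferon response list had a median of −0.15 [−0.28 to −0.09] in endothelial-like cells, at percentile 0.77, or −0.08 with TMM scaling; 3 of 28 members were at least 1.5 times lower and 2 higher, with H2-K1, an MHC class I heavy chain, at −0.62, Isg15 at −0.59 and Ifit3 at 1.29. Immediate-early and dissociation genes were higher (0.21 [0.10 to 0.25], percentile 100), including Klf2 and Ccn1 (0.60) but not Fosb (−0.61). The 34 nuclear genes of oxidative phosphorylation had a median of 0.13 [0.09 to 0.19] at percentile 99.98, with 0 of them 1.5 times apart. Lists close to 0 were arterial genes (0.04 [−0.10 to 0.13]; Edn1, the endothelin precursor, at 0.69 and Gja4, a gap junction gene, at −0.73), type H capillary genes (0.02 [−0.12 to 0.11]), angiogenesis and VEGF signalling (0.02 [−0.05 to 0.12]) and all 20 measured Notch targets (0.05 [−0.06 to 0.26]). The sign of the arterial list turned at a clustering resolution of 0.5 (−0.03), and that of the Notch targets after thinning (−0.07). Transcripts carried over from other cells moved as well: haemoglobin genes stood at 1117 CPM in control and 609 CPM in Notch2em1Ecan endothelial-like cells (6821 and 404 CPM in cluster 4, but 213 and 1323 CPM in cluster 14), granulocyte genes at 24.4 and 64.3 CPM, and fibre genes at 8899 and 10340 CPM.

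**Figure D3:**
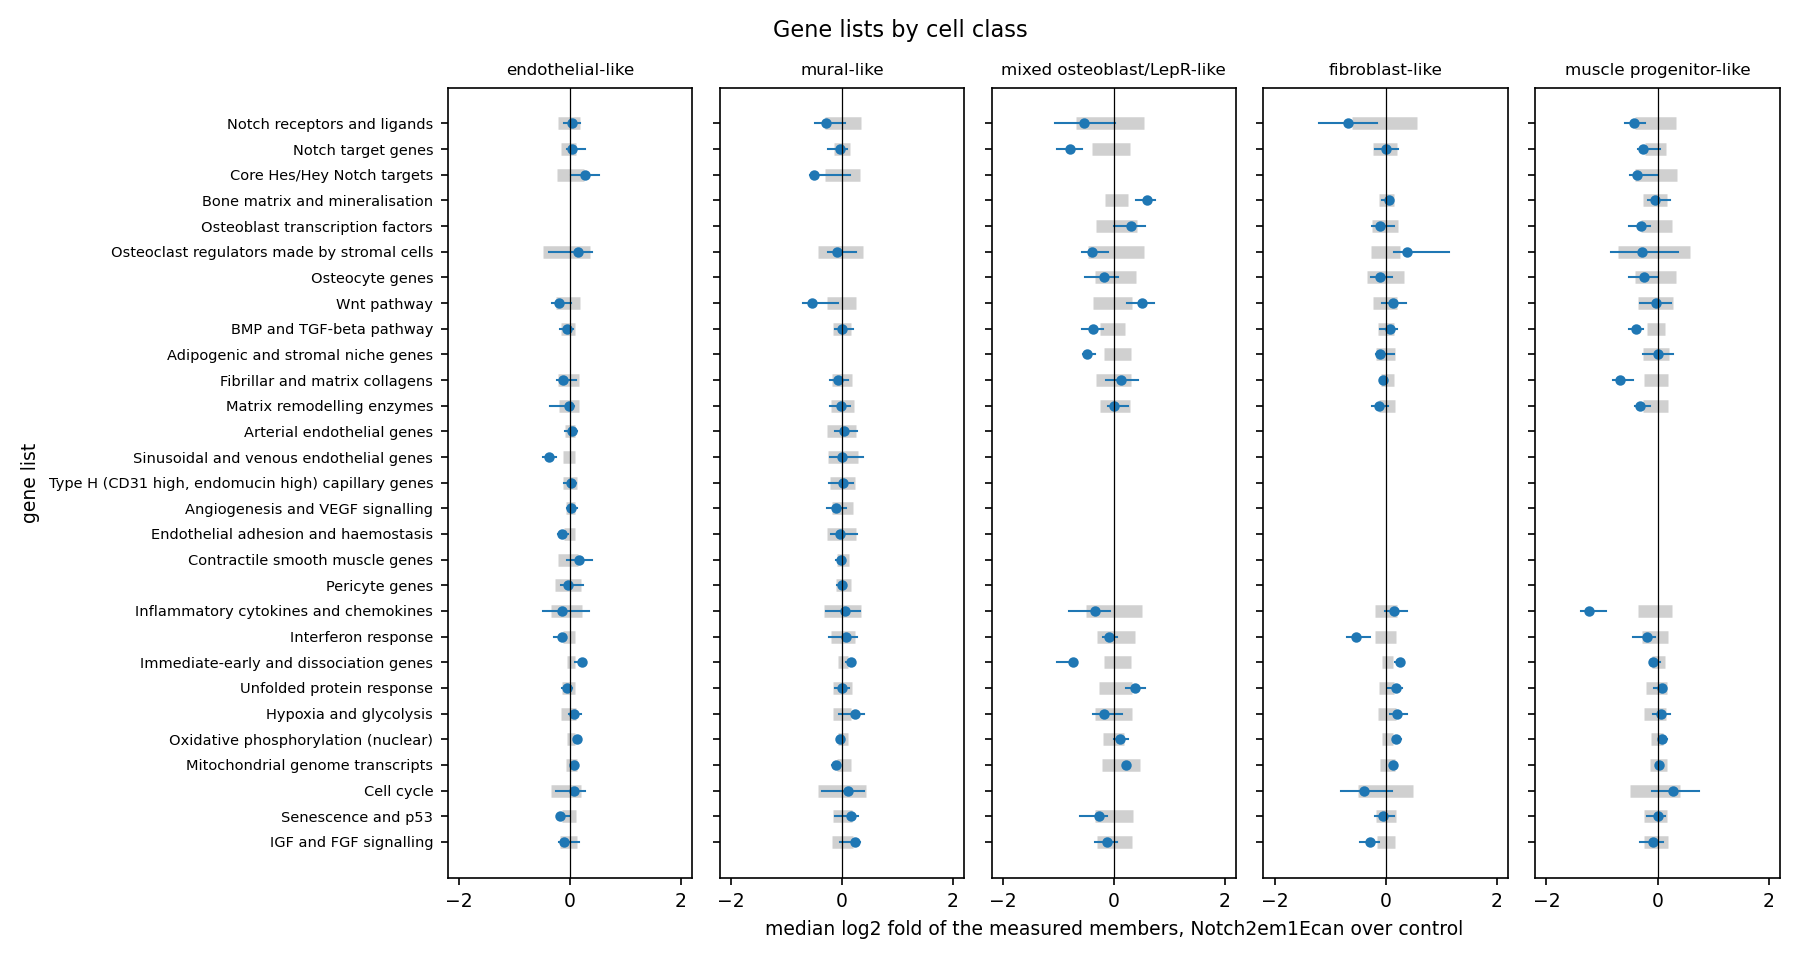
Median log2 fold of each fixed gene list, Notch2em1Ecan over control, per class; dots are medians, blue lines 95% counting intervals and grey bars the middle 95% of 10000 random lists matched on expression. Sinusoidal and venous genes lie at −0.38 in endothelial-like cells, and Notch targets at −0.79 in the mixed osteoblast-lineage and stromal class.

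Mural-like cells, from 826671 control and 897760 Notch2em1Ecan UMIs, held the same mix of a smooth-muscle-like cluster (37.6% and 39.0%) and a pericyte-like cluster (62.4% and 61.0%), within counting error. S100a6 was 2.57-fold higher in the Notch2em1Ecan library [2.29 to 2.89]. Ccn2, a matricellular target of TGF-beta and YAP, was 2.84-fold higher [2.12 to 3.83], but in log2 stood at 0.84 without 5 cells and at 0.06 in the pericyte-like cluster alone. Timp4, an inhibitor of metalloproteinases, was at 1.93, but at 0.02 with a 5% mitochondrial maximum and at 0.63 in the pericyte-like cluster alone. Timp4 is also a leading gene of 4 endothelial-like clusters. Slc6a8, the creatine transporter, was lower at −1.43 [−2.13 to −0.77], or −0.75 in the pericyte-like cluster alone, and Shox2, a homeobox gene, at −1.25 [−2.07 to −0.48], or −0.60 with a 5% mitochondrial maximum. Further lower genes were Dbp (−1.44), Snhg12 (−1.39), Mtf2, a cofactor of Polycomb repression (−1.36), Tef, another clock output gene (−1.34), Slc7a2, a transporter of cationic amino acids (−1.23, or −0.66 without 5 cells), and Lars2 (−0.79). Lgi2 was at −1.74, but at 1.90 with a 5% mitochondrial maximum, and Spty2d1 (−1.24) and Rasl11a (−0.75) stood at −0.33 and −0.10 without 5 cells.

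The other higher genes are made by muscle fibres, namely Apobec2 (2.15), Eef1a2 (2.12), Pgam2 (1.72), Pvalb (1.63), Tnnt3 (1.54), Tnni2 (1.43), Tnnc2 (1.31), Acta1 (1.30) and Mylpf (1.24). Without the 5 cells richest in each, Apobec2 was at 0.33, Pvalb at 0.41, Tnnt3 at 0.57, Pgam2 at 0.62 and Acta1 at 0.63. The values of the other fibre genes are not given here. All 24 named genes of mural-like cells kept their direction, and 5 had an interval that held no difference. Fibre transcripts summed to 4764 CPM in control and 10768 CPM in Notch2em1Ecan mural-like cells, 2.26-fold higher [2.18 to 2.35]. They were 3.17-fold higher in the smooth-muscle-like cluster (4125 and 13064 CPM) and 1.25-fold higher in the pericyte-like cluster (5751 and 7187 CPM).

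Contractile smooth muscle genes were close to 0 as a list (−0.02 [−0.10 to 0.03], 0 of 19 at least 1.5 times apart), with Acta2 at 0.03, Tagln at 0.02 and Myh11, the smooth muscle myosin heavy chain, at −0.39. The list was at 0.51 in the pericyte-like cluster alone and at 0.62 with a 5% mitochondrial maximum. Pericyte genes were likewise close to 0 in median, with Rgs5 at −0.08 and Pdgfrb at −0.10, but stood at −0.50 with a 5% mitochondrial maximum. The 22 measured Notch targets were at −0.03 [−0.24 to 0.09]. The 5 core Hes/Hey genes were at −0.50 [−0.57 to 0.14]. Wnt pathway genes were lower (−0.53 [−0.70 to −0.07], percentile 0), with 4 of 11 at least 1.5 times lower and 1 higher; Tcf7l2, a transcription factor acting with beta-catenin, was at −1.05, the receptor gene Fzd7 at −0.73, Nkd1 at −0.60 and Fzd8 at 0.88. Immediate-early genes had a median of 0.16 [0.07 to 0.22], with Klf4 at 0.74 and Hspb1 at 0.64.

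The mixed osteoblast-lineage and leptin-receptor-stromal class bore on the osteoblast part of the question, with 286733 control and 406821 Notch2em1Ecan UMIs. Its composition differed, since the osteoblast-lineage markers had a median of 0.87 and the stromal markers of −0.41, and few cells held most UMIs of many genes. Genes of bone matrix and mineralisation were higher as a list (0.59 [0.41 to 0.75], percentile 100), 16 of 32 members at least 1.5 times higher and 5 lower. Ibsp, bone sialoprotein, and Col1a1, the collagen I alpha 1 chain, were both at 1.80, Bglap2 at 1.37, Bglap, osteocalcin, at 0.87 and Alpl, the tissue non-specific alkaline phosphatase, at 0.67. Without the 5 cells richest in each, Ibsp was at −0.06 and Col1a1 at 0.21. Mepe and Dmp1, matrix proteins of osteocytes, were lower at −3.40 [−4.32 to −2.59] and −1.19 [−1.42 to −0.97]. Both were highest in a sub-cluster of only 5 control and 5 Notch2em1Ecan cells, described below, so these folds rest on few cells. Wnt pathway genes had a median of 0.52 [0.23 to 0.72], with 6 of 15 higher and 2 lower; Sfrp2, a secreted modulator of Wnt signalling, was at 1.61.

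In the mixed class the 15 measured Notch targets were lower (−0.79 [−1.01 to −0.56], percentile 0.01, or −0.39 after thinning), 10 of them by at least 1.5 times and 0 higher. Heyl was at −1.95, or −0.33 without 5 cells (3 and 4 UMIs), Bhlhe40 at −1.25, Notch3 at −1.11 [−1.83 to −0.40], or −0.69 without 5 cells with an interval that holds no difference, Snai2 at −1.03, Foxc1 at −0.90 and Rbpj, the DNA-binding partner of Notch, at −0.79. Adipogenic and stromal niche genes were at −0.48 [−0.56 to −0.33], with Pparg, the adipogenic regulator, at −1.17, Vcam1 at −0.85, Kitl at −0.66 and the chemokine gene Cxcl12 at −0.51. With each cell at the same weight the niche list was at −0.12. Immediate-early genes were lower (−0.74 [−1.03 to −0.67]), 16 of 25 by at least 1.5 times and 3 higher, among the lower ones Fos (−1.02) and Junb (−1.55, or −0.75 without 5 cells). BMP and TGF-beta genes were at −0.38 [−0.56 to −0.19], with 10 of 29 lower and 2 higher. Other named genes were Smpd3, a sphingomyelinase needed for mineralisation, Adamts18 and Col11a2, at 3.62, 2.74 and 2.24, and at 1.23, 1.34 and 0.69 without 5 cells. Ier3, a stress-responsive gene, was at −2.61, and at −0.95 without 5 cells. Atf3, another, was at −5.07, with 94.6% of its UMIs in 5 cells, so few were left to compare. Ank, a pyrophosphate transporter, was at −1.65 and Fabp4, a fatty-acid-binding protein, at 2.45, and both turned without 5 cells, to 0.54 and −0.48. Endothelial markers stood at 185 and 828 CPM in this class and fibroblast markers at 1897 and 3390 CPM. Carried-over fibre transcripts stood at 7767 and 6288 CPM, haemoglobin at 317 and 165 CPM and granulocyte transcripts at 69.8 and 29.5 CPM.

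When the mixed and osteoblast-lineage-like cells were clustered again, the osteogenic sub-clusters held 23 control and 39 Notch2em1Ecan cells, in a different mix. Sub-cluster 2, richest in Col1a1 (81978 CPM), held 6 and 9 of them, and sub-cluster 5, also rich in it (43572 CPM), 3 and 14. Sub-cluster 3, poor in Col1a1, held 9 and 11, and sub-cluster 0, with most Mepe, 5 and 5. Leading genes of sub-cluster 5 included Mt1, Mt2, Ier2 and Atf3. There bone matrix genes had a median of 0.27 [0.16 to 0.37], percentile 99.93, with 6 of 32 higher and 5 lower by at least 1.5 times, and of 0.28 [0.14 to 0.36] with 1 mix of sub-clusters. Loxl2 and Lox, which cross-link collagen, were at 1.11 [0.70 to 1.55] and 1.08 [0.78 to 1.40], Ibsp at 0.66 and Col1a1 at 0.61. Mepe (−3.82), Dmp1 (−1.93) and Spp1, osteopontin (−0.79), were lower, and the osteocyte list was at −0.51 [−0.83 to −0.12]. With 1 mix of sub-clusters Mepe was at −2.93, Dmp1 at −1.29, Spp1 at 0.01 and the osteocyte list at 0.04 [−0.33 to 0.40]. Notch targets were at −0.11 [−0.65 to 0.27] and Hes1 at 0.33 [−0.24 to 0.94]. In the leptin-receptor-stromal sub-clusters (23 and 19 cells) 7 of 10 measured Notch targets were lower, with a median of −0.68 and an interval below 0, or −0.58 [−0.91 to −0.37] with 1 mix of their sub-clusters, of which sub-cluster 4 held 16 control and 9 Notch2em1Ecan cells. Immediate-early and dissociation genes were lower there too (−0.67, 11 of 20 lower and 0 higher, or −0.35 with 1 mix), while endothelial markers rose from 202 to 1570 CPM, and the niche list was at −0.12 [−0.23 to 0.01]. The osteoblast-lineage-like cluster alone gave 0.13 [0.07 to 0.26] for bone matrix genes, 0.62 [−0.01 to 1.26] for only 4 measured Notch targets, or −0.09 with a 5% mitochondrial maximum, and 1.43 [0.93 to 1.68] for osteocyte genes, but rests on 7 control cells. In it Col1a1 was at 0.29 and Bglap at −0.64.

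Fibroblast-like cells came from 843158 control and 1317570 Notch2em1Ecan UMIs. Cilp, a cartilage matrix protein that binds TGF-beta, was 3.62-fold higher in the Notch2em1Ecan library [3.04 to 4.33] and Lmo2, a transcriptional cofactor, 3.01-fold higher [2.18 to 4.26]. Thbs4, a tendon matrix glycoprotein, was at 5.82 with 56.9% of its UMIs in 5 cells, and at 4.69 without them. Prg4, lubricin, and Col8a1 were at 2.54 and 2.62, and at 0.94 and 1.95 without 5 cells. Thbs4 and Prg4 are on the fixed marker list of tenocyte-like cells. Thbs4 is also a leading gene of the tenocyte-like cluster (16 control and 31 Notch2em1Ecan cells). Whether such cells were mixed into the fibroblast-like class was not tested. Cxcl14 (1.71) and Ccl2 (1.93) were at 0.07 and 0.12 without 5 cells. Lower genes included the sterol synthesis enzymes Sqle (−1.77), Fdps (−1.45) and Idi1 (−1.44, or −0.66 after thinning), the clock output gene Dbp (−1.42), the imprinted gene Mest (−1.37) and Tgfb2, a TGF-beta ligand (−1.05 [−1.32 to −0.78]). Igfbp5 was at −1.45, or −0.56 without 5 cells, and H19 at −2.38, but at 1.22 without 5 cells, from 3 and 12 UMIs. Interferon response genes were lower as a list (−0.54 [−0.70 to −0.28], percentile 0), 7 of 19 by at least 1.5 times and 0 higher, with Ifit2 at −1.06 and Ifi27l2a at −1.40, or −0.63 without 5 cells. IGF and FGF signalling was at −0.29 [−0.47 to −0.13], and Notch targets at 0.01 [−0.19 to 0.23]. Fibre transcripts stood at 2721 and 3919 CPM.

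Muscle-progenitor-like cells, from 985766 control and 1998213 Notch2em1Ecan UMIs, had lower inflammatory cytokine and chemokine genes in the Notch2em1Ecan library (−1.23 [−1.39 to −0.92], percentile 0, 5 of 8 lower and 1 higher by at least 1.5 times). Cxcl1, a neutrophil attractant, was at −1.80 [−2.03 to −1.58], Tnfaip3 at −1.52, Ccl11 at −1.47 and the NF-kappaB inhibitor Nfkbia at −0.99, while Il1b was at 1.23. Among named genes Birc3, another NF-kappaB target, was at −2.17 and Tnfaip6 at −1.84. Collagen genes were lower (−0.67 [−0.80 to −0.45], 8 of 14 lower and 0 higher), with Col1a1 at −1.32, Col15a1 at −0.83 and Col4a1, a basement membrane chain, at −0.63. Fibroblast markers were lower in these cells too, at 2607 CPM in control and 2002 CPM in Notch2em1Ecan (−0.38 [−0.45 to −0.31]). BMP and TGF-beta genes were at −0.38 [−0.52 to −0.26], with Tgfb3 at −0.77, Tgfb2 at −0.75 and Id3, an inhibitor of differentiation, at −0.62. Higher genes included Olfm2 (3 and 93 UMIs, 15.3-fold [5.07 to 75.5]), Slco2a1, a prostaglandin transporter (0 and 55 UMIs, at least 9.04-fold at a floor of 3 counts), and the heat-shock genes Hspa1b (1.59), Hspb1 (1.28) and Hspa1a (1.06). Dcn and Mgp were at 2.03 and 1.66, but at 0.67 and 0.14 without 5 cells, and Osr2 and Cdkn1c at −2.37 and −2.16, but at −0.62 and −0.50. The identity genes Pax7 and Myf5 were at −0.27 and −0.23, and Notch targets had a median of −0.27 [−0.35 to 0.05]. Fibre transcripts stood at 4355 and 4644 CPM.

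Muscle-fibre-like barcodes (224 and 757) held little nuclear RNA, with a median of 0 UMIs of the nuclear transcript Malat1 against 159 and 137 in endothelial-like cells. Their mix of clusters differed: cluster 15, led by fast-fibre genes such as Pvalb and Actn3, made up 32.6% of control and 19.9% of Notch2em1Ecan barcodes, and cluster 10 28.6% and 36.3%. Pdk4, which curbs glucose oxidation in muscle, was 3.04-fold higher in the Notch2em1Ecan library [2.65 to 3.51], or 1.16 in log2 with 1 mix of clusters. Ucp3, a mitochondrial uncoupling protein, was at 0.92 and the cytokine-signalling inhibitor Socs2 at 0.91. Car3, a carbonic anhydrase of slow muscle, and Fabp3 were at 0.73 and 0.62, but at 0.37 and 0.29 with 1 mix of clusters. Malat1 itself was at 3.38, but at 1.08 without 5 barcodes and at −0.01 with a 5% mitochondrial maximum. Smox, a spermine oxidase, was lower at −1.50, Mib1, an E3 ligase that activates Notch ligands, at −1.46 [−1.82 to −1.09], Dbp at −1.29 and the clock repressor Bhlhe41 at −1.05. The 13 mitochondrial transcripts measured had a median of 0.50 [0.40 to 0.58], percentile 100, or 0.21 [0.14 to 0.31] with 1 mix of clusters, with 3 at least 1.5 times higher and 1, mt-Nd6, lower. mt-Co1 was at 0.64 and mt-Cytb at 0.61. Mitochondrial UMIs were scarce here, at medians of 0.0513% per control and 0.121% per Notch2em1Ecan barcode, against 2.16% and 2.43% in endothelial-like cells. Of transcripts carried over from other cells, granulocyte genes were 4.17-fold higher in the Notch2em1Ecan barcodes and haemoglobin genes 1.15-fold [0.911 to 1.46]. Whether carried-over RNA set part of the mitochondrial fold in fibre-like barcodes was not tested. TMM scaling moved the median of all genes in this class by 0.134, and in osteoblast-lineage-like cells by 0.110.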

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

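Each value here was singled out because a class lay on the other side of 0 from another, or because cells appeared that the sort should remove. The value without 5 cells is an alternative chosen after the data were seen. Those cells were picked by the gene's own UMIs, so their removal can by itself shrink or turn a fold. Differences between classes were not tested, since there was 1 library per genotype.

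Hes1 had intervals on opposite sides of 0 in different classes. It was higher in the Notch2em1Ecan library in erythroid-like cells (1.28) and osteoblast-lineage-like cells (2.65). It was lower in endothelial-like (−0.38), fibroblast-like (−0.58), mural-like (−0.50) and muscle-progenitor-like cells (−0.38), and in the mixed osteoblast-lineage and stromal class (−0.67). The erythroid-like value was −1.67 without the 5 cells richest in Hes1 (5 and 1 UMIs left) and −1.69 with a 20% mitochondrial maximum, and the osteoblast-lineage-like value rests on 3 control UMIs. That value was 1.37 without 5 cells. In settings where no mixed class formed, so that the class held 13 to 28 control and 30 to 43 Notch2em1Ecan cells in place of 7 and 18, it was 0.38 (5% mitochondrial maximum), 0.26 (looser minima), 0.25 (at least 1000 genes) and 0.69 (each cell assigned alone).

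Heyl, a Notch target of mural cells and muscle stem cells, was at 0.26 in muscle-progenitor-like cells and −1.95 in the mixed class, from 19 control and 7 Notch2em1Ecan UMIs there. It was −0.11 in muscle-progenitor-like cells after thinning, and in the mixed class −0.33 without 5 cells (3 and 4 UMIs) and −0.16 after thinning (3 and 3 UMIs). Nrarp was at 0.26 in endothelial-like and −0.57 in mural-like cells. The mural-like value was −0.13 after thinning. It turned above 0 with a 5% mitochondrial maximum and in the pericyte-like cluster alone. Interferon response genes had a median of 0.59 in osteoblast-lineage-like and −0.54 in fibroblast-like cells. Wnt pathway genes were at 1.25 in osteoblast-lineage-like cells and 0.52 in the mixed class, against −0.53 in mural-like cells.

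Mixed haematopoietic-like cells made up 1.09% of Notch2em1Ecan cells (23 cells) and 0.414% of control cells (4 cells), although CD45-positive cells were removed by sorting. Their leading genes were immunoglobulin genes and the granulocyte genes S100a8 and S100a9.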

How the results depend on the processing

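The alternatives chosen after the data were seen were 1 mix of clusters within a class, endothelial-like cells without the lymphatic cluster, fibre RNA subtraction, osteogenic sub-clusters, mural clusters apart, mural-like cells without those richest in fibre transcripts, and values without 5 cells. With 1 library per genotype, the spread between mice is unknown, and depth limits Notch2, the core Notch targets and every class under 50 cells. Of 74 values of shares under alternatives, 72 stayed within the main counting interval. Of 242 list medians 210 did, 31 left it and 1 turned from a called direction. These came from only 14 list results, in the endothelial-like, mural-like, osteoblast-lineage-like and mixed classes. All other lists were not run under the filter, depth and scaling alternatives. Among these are the cytokine and collagen lists of muscle-progenitor-like cells, the fibroblast-like interferon list, and every Wnt and immediate-early list. Of 3256 gene values, 2871 stayed within it, 363 left it and 22 turned from a called direction. Called means that the main interval left out 0. Called or not, 5 shares, 28 list medians and 57 gene values had the other sign. Another seed named 160 of 168 of the same genes, resolution 2 162, doublets kept 153, a 20% mitochondrial maximum 136 and thinning 48, where only 71 kept the 50 UMIs the rule asks for. The mixed class did not form, and gave no value, with a 5% mitochondrial maximum, other gene minima, resolution 0.5 or cells assigned alone. In these the osteoblast-lineage-like class held other cells, except at resolution 0.5, where it did not form either. Among the other classes these settings named 88 of 144 (5% maximum), 120 (looser minima), 96 (1000 genes), 141 (resolution 0.5) and 106 (cells alone). The causes of the shifts given next were not tested, except where the setting is fewer cells or subtracted RNA.

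Among scaling choices, TMM put the endothelial-like interferon list at −0.082. Another seed, and keeping doublets, each put bone matrix genes of the mixed class at 0.76. With at least 1000 genes, Notch targets of osteoblast-lineage-like cells were at −0.070, mural contractile genes at −0.11, and the erythroid-like share differed by −1.18 points, against −6.07. With 200 genes and 500 UMIs, where the osteoblast-lineage-like class held 28 control and 41 Notch2em1Ecan cells against 7 and 18, its bone matrix genes were at 0.26, its Notch targets at −0.060, and its share differed by −0.789 points, against 0.126. With members of at least 5 UMIs, the endothelial core Hes/Hey list turned to −0.059. The mean of osteoblast-lineage-like bone matrix genes was 0.45. With a 20% mitochondrial maximum, erythroid-like Hes1 turned to −1.69 and niche genes of the mixed class were at −0.57.

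With cells thinned to 2000 UMIs, medians were −0.070 for endothelial Notch targets, −0.39 for Notch targets and −0.26 for niche genes of the mixed class, −0.65 for sinusoidal and venous genes and 0.61 for osteoblast-lineage-like bone matrix genes. In muscle-progenitor-like cells Dll1 turned to −0.25 (4 and 6 UMIs) and Heyl to −0.11, and mural Notch3 turned to 0.020. Thinning left out 33 control and 50 Notch2em1Ecan endothelial-like and 12 and 2 mural-like cells. With equal weight per cell, erythroid-like Notch2 turned to 0.29 and Grb10 to 0.026, niche genes of the mixed class were at −0.12, osteoblast-lineage-like bone matrix genes at 0.28 and mural contractile genes at 0.10.

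With a 5% mitochondrial maximum, which left 61 control and 69 Notch2em1Ecan mural-like cells, mural lists stood at 0.62 (contractile), −0.50 (pericyte) and 0.12 (Notch targets). Nrarp turned to 0.15 and Lgi2 to 1.90 there. Sinusoidal and venous genes were at −0.24, osteoblast-lineage-like Notch targets at −0.088 and bone matrix genes at 0.30. Mgp in muscle-progenitor-like cells turned to −0.037, Malat1 in fibre-like barcodes to −0.0054, and Sparc and Igfbp7 in erythroid-like cells to −0.98 and −1.48.

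In the pericyte-like cluster alone, mural Nrarp turned to 0.041, with Notch targets at −0.26 and contractile genes at 0.51, which were at −0.15 in the smooth-muscle-like cluster. Without mural-like cells richest in fibre transcripts, contractile genes were at −0.12 and pericyte genes at 0.083. Fibre RNA subtraction took mural Acta1, Apobec2, Tnnt3 and Pgam2 and endothelial Tpm2 to the floor of 3 counts in both libraries, so it gave no value for them. The osteogenic sub-clusters together gave −0.11 for Notch targets and 0.27 for bone matrix genes, and 1 mix of endothelial-like clusters gave −0.15 for sinusoidal and venous genes, which were at −0.39 without the lymphatic cluster. With 1 mix of erythroid-like clusters, Slfn14 turned to −0.057 and Xpo7 to −0.29. Without 5 cells, Ibsp (−0.064), Fabp4 (−0.48) and Ank (0.54) turned in the mixed class, Fabp4 (−0.24), Tmsb4x (−0.35) and Hes1 (−1.67, 5 and 1 UMIs) in erythroid-like cells, and H19 (1.22) in fibroblast-like cells.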

Other observations

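Of the tests reported here, those of library scaling, of Tpm3 with its copy, of free fibre RNA, of genes near Notch2 without Ptpn22 and markers, of named genes near Notch2, and the values with 1 mix of clusters or without 5 cells were chosen after the result was seen. Circadian clock genes differed between the libraries across classes. Dbp, an output gene of the clock, was lower in the Notch2em1Ecan library in 6 of 6 classes with enough UMIs, with a median log2 fold of −1.43. The related output genes Tef and Hlf were lower in 7 of 7 and 4 of 4 classes, with medians of −1.02 and −0.99. Nr1d1 and Nr1d2, which encode REV-ERB repressors, were lower in 6 of 6 classes each, with medians of −0.68 and −0.55. The counting interval lay below 0 in 6 of 6 classes for Dbp, 6 of 7 for Tef, 5 of 6 for Nr1d1, 3 of 6 for Nr1d2 and 2 of 4 for Hlf. The Per genes varied: Per1 was at 0.24 in median, Per3 at −0.44 and Per2 at −0.80 in 2 classes. Genes that peak in the opposite phase were higher in median, Npas2 at 1.02, Arntl at 0.45, Cry1 at 0.36 and Nfil3 at 0.19, while Clock itself was at −0.12. Few of their class values stood clear of counting error. The interval lay above 0 in 1 of 3 classes for Npas2, 2 of 5 for Arntl and 1 of 5 for Cry1. It did so in 0 of 5 for Nfil3 and 0 of 7 for Clock, which had 1 interval below 0.

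Erythroid-like cells, which escaped the sort, held 3247973 control and 2088793 Notch2em1Ecan UMIs. Alas2, the erythroid enzyme of haem synthesis, was higher in the Notch2em1Ecan library at 1.17 [0.88 to 1.46], or 0.56 with a 5% mitochondrial maximum, and Slfn14 at 1.40, or 0.28 without 5 cells. Both are leading genes of erythroid-like cluster 1, which held 9 of 86 control and 12 of 60 Notch2em1Ecan cells. With 1 mix of clusters they stood at 0.20 and −0.06. Haemoglobin genes, which also lead this cluster, stood at 17324 and 38197 CPM. The list of red cell transcripts had a median of 1.17, or 0.06 [−0.01 to 0.10] with 1 mix of clusters. Higher Fabp4 and Tmsb4x rested on few cells. Endothelial markers rose too, from 168 to 294 CPM, and Fabp4 leads several endothelial-like clusters. Among lower genes were Oasl1, an interferon-induced gene (−2.01, or −1.01 with a 5% mitochondrial maximum), Ugt8a (−2.24, or −1.39 without 5 cells) and Vangl1, a planar polarity gene (−1.46). After thinning to 2000 UMIs, 0 of the 24 named genes of this class stayed among them, though only 4 kept 50 UMIs.

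The shared shift of clock genes may reflect collection of the pools at different times of day. A prediction written beforehand was that genes of the opposite phase would then be higher, and their median over 25 gene and class values was 0.294 [0.042 to 0.499]. Library scaling is argued against, since the median log2 fold of all measured genes lay at most 0.0864 from 0 in any of the 7 classes with at least 30 cells per library, while Tef alone had a median of −1.02. A direct effect of the genotype on the clock stays open and was not tested, because each genotype is 1 pool.

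Single genes nearly missing from 1 library may have technical roots. For Rnaset2b, the summed UMIs of it and its copy Rnaset2a had a log2 fold of 0.00945 [−0.11 to 0.13] over all cells, as reads passing between copies would give. That sum held 835 control and 1470 Notch2em1Ecan UMIs, far above the Rnaset2b UMIs of endothelial-like cells. A change in Rnaset2b alone of that size would hardly move the sum, so the value cannot tell shared reads from such a change. For Tpm3-rs7 and Tpm3 the median of the summed UMIs was 0.0106 over classes, but ran from −0.39 to 0.43, so that sharing of reads cannot be told apart from a change in either gene. For Ptpn22, a stretch of another strain's chromosome carried along with the Notch2 allele would raise the share of differing genes nearby. Of 209 genes within 10 Mb of Notch2, 13 (6.22%) were at least 2 times apart in endothelial-like cells, against 3.91% elsewhere, a ratio of 1.59 [0.858 to 2.66], which leaves this open. These 13 included Ptpn22 itself and marker genes of other classes. Without such genes 7 of 203 (3.45%) differed, against 3.73% elsewhere, a ratio of 0.925 [0.375 to 1.87]. Among the 24 named endothelial genes, however, 4 lie in this region (Ptpn22, S100a16, S100a6 and Tpm3), where 0.480 would be expected from the genes the rule could take. Without Ptpn22, which prompted the test, and Tpm3, which has the copy, 2 of 22 did against 0.433. In erythroid-like cells 3 did, in mural-like and fibroblast-like cells 1 each, and in the other 3 classes 0. S100a6 was higher in mural-like cells (1.36) but lower in muscle-progenitor-like cells (−0.48). The values thus go both ways, and a carried-along region cannot be told apart from other causes with 1 pool per genotype.

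The higher fibre transcripts of the Notch2em1Ecan mural-like cells could come from free fibre RNA or from a few droplets with fibre material. Free RNA would raise every class alike, but the mural-like fold exceeded the median of 5 other classes, 0.216, by 0.960 [0.907 to 1.01] in log2. The bracket covers the mural-like counts only. Those 5 classes had at least 30 cells per library. They ran from −0.30 in the mixed osteoblast-lineage and stromal class to 0.53 in fibroblast-like cells. Within mural-like cells the fold was 1.66 in the smooth-muscle-like and 0.32 in the pericyte-like cluster. Smaller classes ranged from −0.61 in mixed haematopoietic-like to 1.56 in Schwann-like cells, so they were not alike either. These values argue against free RNA as the only source, and a part of the rise from it stays open. Without the tenth of cells richest in fibre transcripts, leaving 98 control and 106 Notch2em1Ecan cells, the fold was 0.280 [0.207 to 0.353], which is consistent with a few such droplets. A change in the mural cells themselves was not tested apart from this.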
